A study of Homo sapiens with 9 samples.

How the data were processed

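RNA sequencing was done on 9 libraries from VCaP, an established human prostate cancer cell line. Per the labels, cells were transfected for 4 days with a control siRNA or with 1 of 2 siRNAs against KMT2C, with 3 libraries per group, on an Illumina instrument. The siRNA sequences are not given in the sources used here, nor whether the replicates were separate cultures, and the p-values measure only spread between these samples, which may be technical.

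The values came from a single table of 60612 genes. Its count columns hold expected counts: per the file headers they are counts, and the deposited values are whole numbers that were not normalized. In genes with 1 transcript and more than 50 counts they equal FPKM times length times a constant per library within 2%, and low values pile up at 4, 8, 12, 15 and 19, so close to 4 counts stand for 1 sequenced fragment. Values of 1, 2 and 3 were also common (6199, 4621 and 3800, against 7580 at 4), so the numbers of fragments below are approximate. The expected counts were rounded to whole numbers before the test, which changed no value. Its other columns hold FPKM (fragments per kilobase of transcript, scaled for sequencing depth), calculated by the authors, with genes without counts listed at 0.0001. Per the submitters' processing notes, Bowtie 0.12.2 and the genome builds mm8 and hg38 were named without a role. The design text calls the RNA retinal, which the sample labels do not. The counting tool and the annotation version are not given in the sources used here. Of the gene identifiers, 58394 are in GENCODE release 29 on GRCh38, and 72.7% of these have the same start and end there while 99.98% overlap, so the coordinates given are on GRCh38. Library totals ranged from 58462215 to 70726213 counts. The table also gives KEGG pathway names per gene, which were used as sets.

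Genes with an FPKM of at least 1 in at least 3 libraries were tested (12830 genes). The design written before the data were examined named limma on log2(FPKM + 1), or edgeR if counts were present, so the main test was edgeR 4.0.16 with TMM scaling and the quasi-likelihood F test on the counts (R 4.3.3, the data.table package, version 1.17.8). It was fitted on all 9 libraries with 1 mean per group, with 2-sided tests and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0437. The contrasts were siRNA 1 against control, siRNA 2 against control, the average of both siRNAs against control, and siRNA 1 against siRNA 2, which tests the difference of the 2 effects. Log2 fold changes are given with a standard error (SE) equal to their size over the square root of F, and expression as mean FPKM with its standard deviation (SD). For KMT2C an exact 2-sided permutation test of log2 CPM (counts scaled to an equal library size) was run as well.

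The 32 gene lists fixed before the data were examined were H3K4 methyltransferase complexes, androgen-induced, androgen-repressed, luminal prostate epithelium, basal prostate epithelium, neuroendocrine, mesenchymal transition, ERG-associated, homologous recombination and Fanconi, DNA replication, mitosis, p53 targets, interferon-stimulated, MHC class I presentation, NF-kappaB, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, ER stress and integrated stress response, heat shock, cytosolic ribosomal proteins, ribosome biogenesis, nuclear OXPHOS (oxidative phosphorylation) subunits, mitochondrially encoded, replication-dependent histones, immediate early, apoptosis regulators, Polycomb, DNA methylation, small RNA machinery, TGF-beta and YAP targets, and other cell types. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a contrast. Camera was also run on 268 KEGG pathways with at least 15 tested genes, which was decided after the data were seen.

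Genes were named by a rule fixed before the data were examined. It took KMT2C and the H3K4 list, and the 10 largest rises and falls called with both siRNAs, ranked by the smaller change, leaving out clone and assembly identifiers. It also took up to 4 members per list with the smallest adjusted p for the average, the 5 largest differences between the siRNAs each way, and the 5 largest changes each way per siRNA. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen. Where a gene's libraries in a group were all at 0, the fold is a lower bound against 3 fragments over the group. With 1 to 3 fragments in a group the ratio of counts is given with a 95% exact counting interval. The interval uses fragments (counts divided by 4, rounded, at least 1), so the ratio need not lie at its centre. Intervals and floors cover counting error only.

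The pipeline was tested on simulated data first. Counts were drawn with means pooled over the 9 libraries and the fitted dispersions. With changes added to 67 genes at a log2 size of 1, 59.7% were recovered for siRNA 1, 59.7% for siRNA 2, 67.2% for the average and 79.1% for the difference. At a log2 size of 0.5 the share recovered was 8.96%, 5.97%, 17.9% and 7.46%. False calls were 4 of 114, 4 of 110, 3 of 125 and 4 of 126. So few calls make the adjusted threshold stricter than in the data, so the shares recovered do not carry over to the data. The overlap of the 2 siRNA contrasts was set against 20 simulated draws of unchanged groups sharing the same controls.

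Alternatives chosen before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter, FPKM of at least 5, filterByExpr, a replicate block, only the libraries compared, limma on log2(FPKM + 1) and log2(FPKM + 0.1), 3 other scalings of FPKM, eBayes without trend, a minimum absolute log2 fold change of 1, and leaving out each library. Added after the data were seen were counts divided by 4, scaling to library totals, leaving out mitochondrial genes, and offsets for transcript length and GC content. No sample column was left out. Reads, splicing and the parts of a gene that the siRNAs target were not analysed here.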

Results

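The transcriptome of VCaP cells was measured by RNA sequencing. VCaP is a human prostate cancer line that carries the TMPRSS2-ERG gene fusion. Cells were transfected for 4 days with a control siRNA or with siRNA 1 or siRNA 2 against KMT2C, which encodes a histone H3 lysine 4 (H3K4) methyltransferase, with 3 libraries per group. Library totals were 58462215 to 70726213 estimated counts, and 24406 to 25318 genes had counts above 0. Mitochondrial genes took 10.6% ± 0.501 of the counts in control cells, 9.02% ± 0.698 with siRNA 1 and 12.05% ± 0.119 with siRNA 2 (SD, n = 3). The first principal component held 44.6% of the variance and the second 21.2%. Below, FPKM values are mean ± SD with n = 3, and log2 fold changes carry ± SE and come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

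KMT2C (ENSG00000055609, GRCh38 chromosome 7, 152134922 to 152436003, minus strand) fell with both siRNAs. Its level was 13.7, 12.1 and 12.9 FPKM in the control libraries, 1.54, 1.80 and 2.28 with siRNA 1, and 1.72, 1.64 and 1.73 with siRNA 2. Of the control level 14.3% remained with siRNA 1 and 12.7% with siRNA 2. The log2 fold change was -2.81 ± 0.13 with siRNA 1 (adjusted p = 4.56e-06) and -2.98 ± 0.13 with siRNA 2 (adjusted p = 8.76e-07). The difference between the siRNAs, 0.17 ± 0.12, did not pass the test (adjusted p = 0.309). In an exact 2-sided permutation test of both siRNAs against control, p was 0.0119, the smallest that 84 splits allow. For a single siRNA the exact permutation p was 0.1, the smallest that 20 splits of 3 against 3 allow. KMT2C has partial duplicate copies elsewhere in the genome, and how reads were shared among them is not known here.

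**Figure D1:**
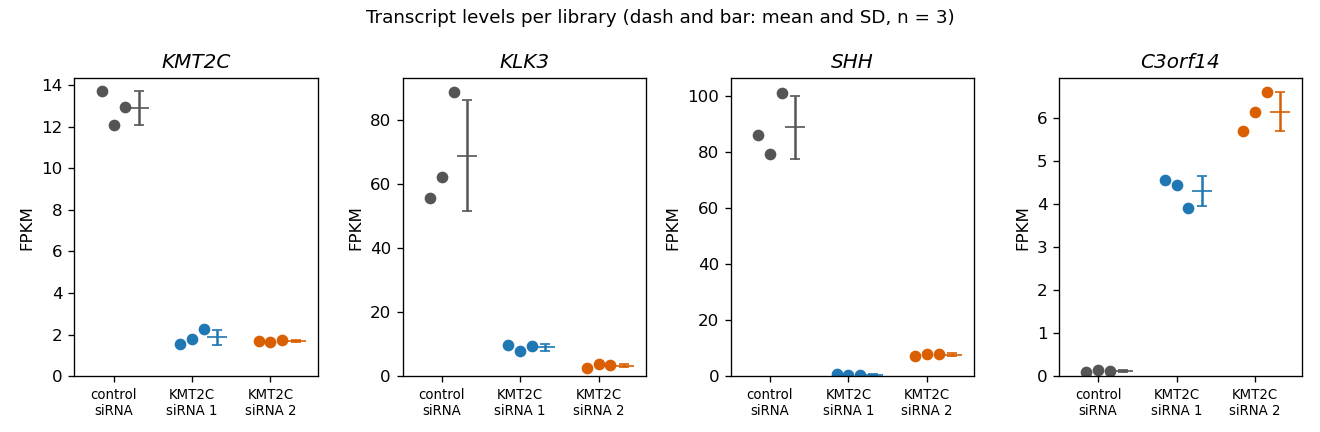
Expression in FPKM (vertical axis, linear) of KMT2C, KLK3, SHH and C3orf14 with control siRNA, siRNA 1 and siRNA 2, with a point per library and a dash and bar for the mean and SD (n = 3). KMT2C lies between 12.1 and 13.7 FPKM in the control libraries and between 1.54 and 2.28 in the libraries of both siRNAs.

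The comparison of both siRNAs with control asks which genes change, in the average of the 2 sequences, when KMT2C is lowered. A call in the average can come from 1 siRNA alone or against the other. It called 6097 genes, while 3317 were called with both siRNAs in the same direction. The prostate genes KLK3, KLK2 and TMPRSS2, the hedgehog ligand genes SHH and IHH and the sterol synthesis gene MSMO1 fell with each siRNA, while the ribosomal protein gene RPL11 and the nucleolar gene NOLC1 rose with each. KLK3 (GRCh38 chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, dropped from 68.9 ± 17.4 FPKM to 9.10 ± 1.02 with siRNA 1 and 3.39 ± 0.579 with siRNA 2, 7.70-fold and 21.1-fold lower. SHH (chromosome 7, 155799980 to 155812463), which encodes a hedgehog ligand, dropped from 88.7 ± 11.2 FPKM to 0.549 ± 0.191 and 7.74 ± 0.468, 163-fold and 11.9-fold lower. Its relative IHH (chromosome 2, 219054424 to 219060921) went from 36.2 ± 8.15 FPKM to 1.78 ± 0.348 and 0.405 ± 0.0705, 20.7-fold and 92.1-fold lower.

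Ranked by the smaller of the 2 changes among genes called with both siRNAs in the same direction, C3orf14 (chromosome 3, 62319015 to 62336213) had the largest rise, by 4.99 ± 0.16 on the log2 scale with siRNA 1 and 5.48 ± 0.16 with siRNA 2, from 0.130 FPKM in control cells. RORB, an orphan nuclear receptor gene, rose by 4.14 ± 0.27 and 6.49 ± 0.29, and the adhesion receptor gene ADGRF5 by 2.87 ± 0.42 and 5.81 ± 0.46. SH3GL3 rose by 3.14 and 3.55, SH3BGRL by 3.11 and 2.89, the globin gene HBQ1 by 2.76 and 2.79, ARHGAP20 by 2.59 and 4.18, and PI3, which encodes the protease inhibitor elafin, by 2.96 and 3.85. Apart from short RNA genes, the largest fall was in S1PR3, a sphingosine 1-phosphate receptor gene (-4.44 and -6.12). IHH and SHH, described above, ranked below S1PR3 and are left out of the order here. S1PR3 was followed by the antisense RNA B3GALT5-AS1 (-4.32 and -5.77), IGSF21 (-4.08 and -4.12) and the glycosyltransferase gene B3GNT6 (-5.98 and -4.07). Next came the zinc finger gene ZNF536 (-3.82 and -4.35) and SCUBE2, whose product helps release hedgehog ligands (-3.71 ± 0.14 and -6.19 ± 0.16). Adjusted p for these genes lay between 1.33e-07 and 8.79e-04. The short RNA genes SNORD30, MIR3648-1, SNORD22 and MIR3131 also met the ranking, at very low counts. SNORD30 was 22.8-fold higher with siRNA 1 (95% counting interval 3.80 to 959) and 17.7-fold higher with siRNA 2 (2.71 to 716), from 4 counts over all control libraries. It and SNORD22 lie within SNHG1, whose reads cannot be separated from theirs here. MIR3648-1 was 15.6-fold higher (4.50 to 150.0) and 17.9-fold higher (5.21 to 171). SNORD22 was 62.3-fold lower (10.7 to 2479) and 84.5-fold lower (10.9 to 2525). MIR3131 was at 0 with siRNA 1, at least 3.82-fold lower, and 23.6-fold lower with siRNA 2 (1.68 to 496).

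Luminal and androgen-regulated genes moved with these. Of 13 tested genes of the luminal prostate epithelium, 11 fell in the average of both siRNAs and none rose (12 fell adjusted over the list alone), with a median log2 fold change of -0.92 (camera adjusted p = 3.13e-08, and adjusted p = 0.0302 with an estimated correlation). GATA2, a luminal transcription factor gene, fell by 0.82 and 1.71 with siRNA 1 and siRNA 2, ACP3, which encodes prostatic acid phosphatase, by 1.47 and 0.59, the E-cadherin gene CDH1 by 1.11 and 1.44, and the epithelial regulator gene GRHL2 by 0.53 and 0.58. SPDEF, an ETS factor gene of secretory cells, rose by 0.41 with siRNA 1 and fell by 2.25 with siRNA 2. CLDN4 was uneven in the control libraries, at 22.5 ± 31.0 FPKM. CDH1 and CLDN4 were chosen after their values were seen. Among 23 tested androgen-induced genes, 12 fell and 3 rose, with the same counts adjusted over the list alone, and the median was -0.28 (camera adjusted p = 8.91e-06, but adjusted p = 0.0541 with an estimated correlation). TMPRSS2, a membrane serine protease gene (chromosome 21, 41464305 to 41531098), fell by 2.35 ± 0.05 and 1.22 ± 0.05, the kallikrein gene KLK2 by 1.52 ± 0.07 and 2.02 ± 0.07, and SLC45A3, which encodes prostein, by 1.78 ± 0.10 and 1.65 ± 0.10. FKBP5, an androgen-induced chaperone gene chosen after its values were seen, rose by 1.02 and 1.55.

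Of 8 androgen-repressed genes 4 rose and 3 fell, with the same counts adjusted over the list alone. Their median was 0.26 and their mean -0.37, and camera's direction followed the mean (adjusted p = 0.119). ACKR3, a chemokine receptor gene, fell by 3.53 and 3.12, and AKR1C3, an androgen-synthesis enzyme gene, by 1.15 and 3.37, while HSD17B6, whose exons overlap PRIM1, rose by 0.79 and 0.70. ERG, the ETS factor gene in the fusion of these cells, was 63.9 FPKM in control cells, 33.4 with siRNA 1 and 32.3 with siRNA 2, and fell by 0.96 ± 0.05 and 1.04 ± 0.05. The 12 tested ERG-associated genes had 4 rises and 4 falls, also adjusted over the list alone (median -0.15, camera adjusted p = 0.961). CRISP3, a secretory protein gene, rose by 1.40 and 0.78, and PDE3B, a phosphodiesterase gene, by 0.75 and 1.11. LEF1, a Wnt pathway transcription factor gene, fell by 1.03 with siRNA 1 and had 0.16 with siRNA 2, which did not pass the test.

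In the average of both siRNAs, 20 of 24 cholesterol synthesis genes fell and 1 rose, the same adjusted over the list alone (median -0.73, camera adjusted p = 3.13e-08, but adjusted p = 0.321 with an estimated correlation). The sterol oxidase gene MSMO1 went from 73.2 FPKM to 16.7 and 29.4, a fall by 2.15 ± 0.07 and 1.37 ± 0.07 on the log2 scale. LSS, lanosterol synthase, fell by 1.47 and 0.43, and MVK, mevalonate kinase, by 1.21 and 0.34. MVK has exons that overlap MMAB on the opposite strand. PMVK, phosphomevalonate kinase, was the member that rose (0.78 and 0.34), chosen after its values were seen. In fatty acid synthesis 9 of 14 genes fell and 1 rose, the same adjusted over the list alone (median -0.47, camera adjusted p = 0.00626, but adjusted p = 0.649 with an estimated correlation). With siRNA 2 alone neither list passed, with 15 falls and 4 rises in cholesterol synthesis (camera adjusted p = 0.0516) and 9 falls and 1 rise in fatty acid synthesis (camera adjusted p = 0.0566), the same counts adjusted over the list alone. FASN, fatty acid synthase, fell by 0.98 and 1.09, the desaturase gene SCD by 1.07 and 0.75, ACSS2, an acetyl-CoA synthetase, by 0.34 and 0.80, and FADS2, which overlaps FADS1 and FEN1, by 0.88 and 1.08.

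Among 75 cytosolic ribosomal protein genes 42 rose in the average and none fell (45 rose adjusted over the list alone), with a median of 0.27 (camera adjusted p = 2.96e-06, but adjusted p = 0.729 with an estimated correlation). RPL11 rose by 1.20 and 0.89, RPL32 by 0.57 and 0.80, RPL12 by 0.58 and 0.25, and RPL17, in a read-through locus, by 0.78 and 0.58. In ribosome biogenesis 15 of 26 genes rose and 1 fell (16 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 6.15e-04, but adjusted p = 0.321 with an estimated correlation). With siRNA 2 alone this list, with 11 rises and 1 fall, also adjusted over the list alone, did not pass (camera adjusted p = 0.0566). NOLC1, a nucleolar phosphoprotein gene, rose by 1.98 ± 0.05 and 1.51 ± 0.05, DKC1, the pseudouridine synthase dyskerin, by 0.72 and 0.48, POLR1B, an RNA polymerase I subunit, by 0.69 and 0.85, and NOP16, which overlaps HIGD2A, by 0.85 and 0.77. GNL3, nucleostemin, was the member that fell in the average (-0.23), chosen after its values were seen. Nuclear OXPHOS subunit genes had 20 rises and no fall among 43, the same adjusted over the list alone (median 0.26, camera adjusted p = 0.00119, but adjusted p = 0.729 with an estimated correlation). NDUFS4, of respiratory complex I, rose by 0.41 and 0.70, UQCRC2, of complex III, by 0.46 and 0.63, and ATP5MC1, of the ATP synthase, by 0.49 and 0.57. The mitochondrial share of counts, by contrast, was 1.55 points lower than control with siRNA 1 and 1.47 points higher with siRNA 2. Of the 13 mitochondrially encoded mRNAs only MT-ND6 fell in the average (median -0.04, camera adjusted p = 0.961, 1 fall adjusted over the list alone), by 0.58 with siRNA 1, with 0.01 for siRNA 2. That call was lost under quantile normalization.

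**Figure D2:**
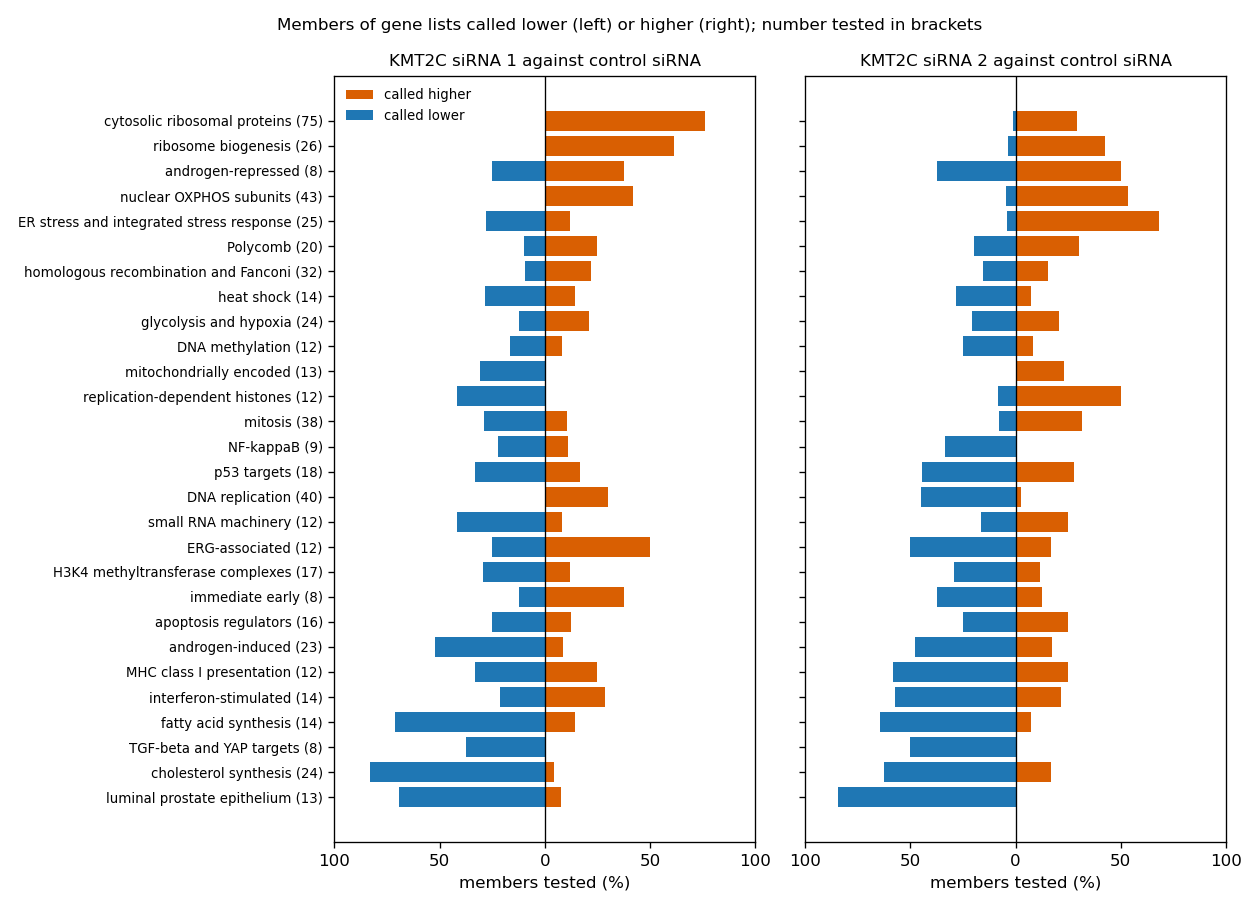
Percent of tested members (horizontal axis) called lower (left bars) or higher (right bars) with siRNA 1 and with siRNA 2 against control, for each gene list with at least 8 tested members, whose number is in brackets. Of the 75 cytosolic ribosomal protein genes 57 were higher with siRNA 1 and 22 with siRNA 2, and of the 13 luminal genes 9 and 11 were lower.

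Of the 17 tested partners of KMT2C and members of related H3K4 methyltransferase complexes, 5 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.19, camera adjusted p = 0.322). NCOA6, a subunit of the KMT2C and KMT2D complexes with exons overlapping PIGU, fell by 0.46 and 1.28, and the methyltransferase gene SETD1B by 0.63 and 0.50. WDR5, a shared core subunit, rose by 0.24 and 0.25. KMT2D, the closest relative of KMT2C, had 0.01 ± 0.08 with siRNA 1 and fell by 0.58 ± 0.08 with siRNA 2 (adjusted p = 3.55e-04), and MEN1, menin, had -0.21 and fell by 0.94. KDM6A, the H3K27 demethylase of the complex, fell by 0.63 with siRNA 1, with 0.11 for siRNA 2, and KMT2A and KMT2B fell with siRNA 1 by 0.54 and 0.38, with -0.08 and 0.08 for siRNA 2. ASH2L rose by 0.39 and DPY30, which overlaps MEMO1, fell by 0.35 with siRNA 2, against 0.17 and -0.02 with siRNA 1, and SETD1A rose by 0.22 with siRNA 1, with 0.10 for siRNA 2. RBBP5, CXXC1, PAXIP1, WDR82, HCFC1 and PAGR1 passed the test with neither siRNA, with values from -0.36 to 0.09.

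The stress, cell cycle and immune lists had members that moved both ways. Of 25 ER stress genes 10 rose and 3 fell (10 and 4 adjusted over the list alone, median 0.24, camera adjusted p = 0.190). SDF2L1, an ER chaperone cofactor gene, rose by 0.61 and 0.53, and CEBPB, a transcription factor gene, by 0.52 and 1.73. Among 18 p53 targets 5 rose and 7 fell, also adjusted over the list alone (median -0.06, camera adjusted p = 0.0770). BTG2, an antiproliferative gene, fell by 0.79 and 2.52, TP53INP1 by 0.97 and 1.33, and MDM2, which encodes the ubiquitin ligase of p53, by 0.43 and 1.52. The cell cycle inhibitor gene CDKN1A fell by 1.99 with siRNA 2, with -0.39 for siRNA 1. DNA replication had 4 rises and 9 falls among 40 genes (2 and 5 adjusted over the list alone, median -0.07, camera adjusted p = 0.961), and CDC45, a replicative helicase factor, rose by 0.69 with siRNA 1, with 0.29 for siRNA 2. Mitosis had 8 rises and 8 falls among 38 (7 and 8 adjusted over the list alone). Its median was -0.05 with camera's direction up (adjusted p = 0.961), and CENPF, a kinetochore gene, rose by 0.21 and 0.78, CCNB2, cyclin B2, by 0.25 and 0.64, while PLK1, a mitotic kinase, fell by 0.33 and 0.32. CDC20, which activates the anaphase-promoting complex, fell by 0.46 with siRNA 1, with -0.09 for siRNA 2. Of 32 homologous recombination and Fanconi genes 6 rose and 4 fell, also adjusted over the list alone (median 0.02, camera adjusted p = 0.910). BARD1, the partner of BRCA1, fell by 1.06 and 1.00, the recombination gene RAD51D rose by 0.85 and 0.37, and the checkpoint kinase gene CHEK2, which overlaps HSCB, by 0.40 and 0.28.

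Interferon-stimulated genes had 4 rises and 8 falls among 14, also adjusted over the list alone (median -0.37, camera adjusted p = 0.910). The RNA sensor gene IFIH1 rose by 0.84 and 1.19 and the ISG15 protease gene USP18 by 0.64 and 0.84, while HERC6 fell by 0.52 and 0.64. MHC class I presentation had 3 rises and 6 falls among 12, also adjusted over the list alone (median -0.29, camera adjusted p = 0.731), with the peptide transporter genes TAP1 (0.33 and 0.42) and TAP2 (0.83 and 0.91) higher and TAPBP, tapasin, (-0.82 and -0.91) lower. HLA-C, a paralog that overlaps HLA-B in the annotation, fell by 1.51 with siRNA 2, with -0.53 for siRNA 1. Of 9 NF-kappaB genes 1 rose and 3 fell, also adjusted over the list alone (median -0.06, camera adjusted p = 0.291), and BIRC3, an apoptosis inhibitor gene, fell by 2.34 ± 0.16 and 3.77 ± 0.17. The chemokine gene CCL2 fell by 1.87 with siRNA 2, with -0.39 for siRNA 1, and NFKB2 fell by 0.56 with siRNA 1, with -0.12 for siRNA 2. Glycolysis and hypoxia had 6 rises and 6 falls among 24, also adjusted over the list alone. The median was -0.01 with camera's direction up (adjusted p = 0.961), PFKL and PFKP, phosphofructokinases, rose by 0.80 and 0.75 and by 1.26 and 1.26, and ADM, adrenomedullin, fell by 2.17 and 1.01.

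Heat shock genes had 1 rise and 5 falls among 14 (2 and 5 adjusted over the list alone), with a median of -0.01 and camera's direction up (adjusted p = 0.997). The mitochondrial chaperone gene HSPD1, whose exons overlap HSPE1 on the opposite strand, rose by 0.90 and 0.73. DNAJB1 and HSPA4, cytosolic chaperone genes, fell by 0.23 and 0.44 and by 0.15 and 0.24, and HSPA1B, a heat-inducible paralog, by 0.36 with siRNA 1, with -0.18 for siRNA 2. Immediate early genes had 1 rise and 1 fall among 8, also adjusted over the list alone (median -0.21, mean 0.00, camera adjusted p = 0.961). DUSP1, a MAP kinase phosphatase gene, rose by 1.22 and 1.09, EGR1 and JUN fell by 0.67 and 0.57 with siRNA 2, against -0.34 and 0.09 with siRNA 1, and KLF4 fell by 0.66 with siRNA 1, with -0.20 for siRNA 2. Apoptosis regulators had 3 rises and 5 falls among 16, also adjusted over the list alone (median -0.23, camera adjusted p = 0.703). MCL1, a survival factor gene, fell by 1.07 and 0.40, the pro-death genes BIK by 0.86 and 0.96 and BMF by 2.45 and 3.65, while CASP8, an initiator caspase gene, rose by 0.66 and 0.46. TGF-beta and YAP targets had 5 falls and no rise among 8 (6 falls adjusted over the list alone, median -0.55, camera adjusted p = 0.119). ID2, which inhibits helix-loop-helix factors, fell by 0.80 and 0.57, its relatives ID1 and ID3 by 0.90 and 0.84 with siRNA 2, against -0.19 and -0.26 with siRNA 1, and AMOTL2 by 1.19 with siRNA 1, with -0.40 for siRNA 2.

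Polycomb genes had 6 rises and 3 falls among 20, also adjusted over the list alone (median 0.04, camera adjusted p = 0.731), with CBX2 (0.51 and 0.35) and PCGF6 (0.68 and 0.63) higher with both siRNAs and BMI1 (-0.24 and -0.19) lower. CBX7 rose by 0.87 with siRNA 2, with -0.19 for siRNA 1. DNA methylation genes had 1 rise and 4 falls among 12, also adjusted over the list alone (median -0.03, camera adjusted p = 0.961). With siRNA 2, TET1 rose by 1.34 and TET2 and DNMT1 fell by 0.71 and 0.47, against 0.32, -0.34 and -0.01 with siRNA 1. Small RNA machinery had 2 rises and 4 falls among 12, also adjusted over the list alone (median -0.13, camera adjusted p = 0.864). DROSHA, which cuts primary microRNAs, rose by 0.68 and 0.61 and AGO4, an Argonaute gene, fell by 1.00 and 0.46. DICER1 fell by 1.09 with siRNA 1, with -0.36 for siRNA 2, and TARBP2 by 0.78 with siRNA 2, with -0.14 for siRNA 1. Replication-dependent histones had 3 falls among 12 and no rise (2 falls adjusted over the list alone, median -0.04, camera adjusted p = 0.961).

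Lineage markers outside the luminal type were few. Basal epithelium had 2 tested genes, of which ITGA6, an integrin gene, fell in the average (also adjusted over the list alone, median -0.45, camera adjusted p = 0.731). In the average neither a rise nor a fall was called among 3 neuroendocrine genes, also adjusted over the list alone (median 0.05, camera adjusted p = 0.961). Of the 3, 2 fell with siRNA 1 and 2 rose with siRNA 2, also adjusted over the list alone. SYP, synaptophysin, fell by 0.58 with siRNA 1, with -0.02 for siRNA 2, while INSM1 rose by 0.53 with siRNA 2, with -0.04 for siRNA 1. The 2 tested genes of mesenchymal transition, TNC and SNAI1, were higher in the average, also adjusted over the list alone (median 1.97, camera adjusted p = 0.0658). Both rose with siRNA 2, while neither passed the test with siRNA 1. The call of SNAI1 in the average was lost without CTRL replicate 1 or 3, siRNA 1 replicate 2 or 3, or siRNA 2 replicate 1 or 3. Of 4 markers of other cell types 2 rose and none fell (2 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 0.627). CD14, a monocyte gene, rose from 0.516 FPKM to 1.49 with siRNA 1 and 1.498 with siRNA 2, the stromal gene LUM fell by 0.85 with siRNA 1 and rose by 2.92 with siRNA 2, and ALB, albumin, fell by 0.94 with siRNA 1, with -0.37 for siRNA 2. ACTA2, a smooth muscle gene that overlaps FAS, had 0.49 and -0.09 and passed neither test.

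Over all 12830 tested genes, 3317 were called with both siRNAs in the same direction, 1696 higher and 1621 lower, where independent calls would give 664 and 655. Of these, 295 were higher and 338 lower by at least 2-fold with each siRNA. Another 416 genes were called in opposite directions, 242 higher with siRNA 1 and lower with siRNA 2 and 174 the reverse. Independent calls would give 679 and 640, but the calls are not independent, since the control libraries are shared. Of the 416 genes, 21 changed by at least 2-fold with each siRNA. Without CTRL replicate 1, 277 genes were called in opposite directions. The average of both siRNAs called 6097 genes, 2950 higher and 3147 lower, and which of these was larger turned with the scaling. Camera called 7 of the 32 lists for the average, of which the luminal list alone held with an estimated correlation. Fry called 20, and its p tests whether a list's genes move, on balance, one way, without comparing them with other genes. Both contrasts share the same 3 control libraries. In 20 simulated draws of unchanged groups the correlation across genes of the fold changes reached 0.510 on average (0.437 to 0.622) against 0.595 in the data, although genes are not independent replicates. No gene was called in the same direction in the draws, but each siRNA called at most 1 gene there. The draws therefore cannot tell how much of the overlap of calls comes from the shared controls. Values of genes whose exons overlap another annotated gene are uncertain, and besides those described so far these were VLDLR, ASNS, DNAJB1, TARBP2, ID2, KMT2B, PAXIP1, WDR82 and PAGR1.

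**Figure D3:**
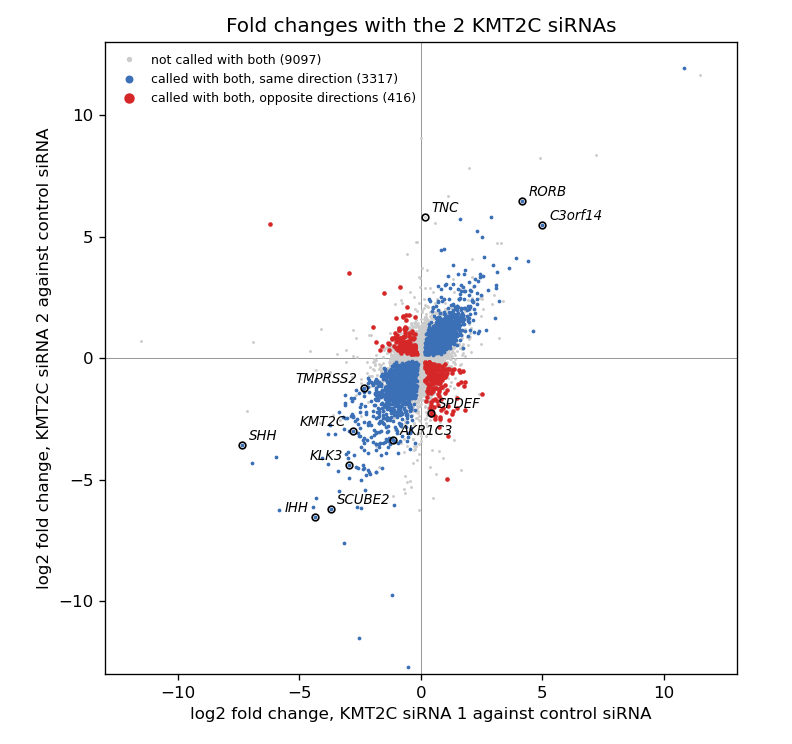
Log2 fold change of each tested gene with siRNA 1 (horizontal) and siRNA 2 (vertical) against control, with points coloured by whether both siRNAs called the gene in the same direction (3317), in opposite directions (416) or not. SHH lies at -7.35 and -3.57 and SPDEF at 0.41 and -2.25.

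With siRNA 1 alone, most cholesterol synthesis and androgen-induced genes fell and most ribosomal protein genes rose. Of the 24 cholesterol synthesis genes 20 fell and 1 rose, the same adjusted over the list alone (median -1.07, camera adjusted p = 3.02e-18, but adjusted p = 0.125 with an estimated correlation). Androgen-induced genes had 12 falls and 2 rises among 23, also adjusted over the list alone (median -0.33, camera adjusted p = 4.55e-09, and adjusted p = 0.0319 with an estimated correlation), and luminal genes 9 falls and 1 rise among 13 (median -0.54, camera adjusted p = 7.85e-05, but adjusted p = 0.0645 with an estimated correlation). Cytosolic ribosomal protein genes had 57 rises and no fall among 75 (58 adjusted over the list alone, median 0.44, camera adjusted p = 4.74e-12, but adjusted p = 0.545 with an estimated correlation). CXCL11, an interferon-induced chemokine gene, was among the 5 largest rises, by 3.22 ± 0.34 (adjusted p = 1.74e-04), and rose by 2.34 with siRNA 2.

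Ribosome biogenesis had 16 rises among 26 with siRNA 1 (18 adjusted over the list alone, median 0.35, camera adjusted p = 2.47e-06, but adjusted p = 0.125 with an estimated correlation). Nuclear OXPHOS subunits had 18 rises among 43, also adjusted over the list alone (median 0.21, camera adjusted p = 0.00541, but adjusted p = 0.617 with an estimated correlation), a call lost with offsets for transcript length and GC content. Fatty acid synthesis had 10 falls and 2 rises among 14, also adjusted over the list alone (median -0.37, camera adjusted p = 0.00150, but adjusted p = 0.545 with an estimated correlation). Replication-dependent histones had 5 falls among 12, also adjusted over the list alone (median -0.54, camera adjusted p = 0.0430, but adjusted p = 0.498 with an estimated correlation), and this call was lost when CTRL replicate 2, siRNA 1 replicate 3 or any 1 siRNA 2 library was left out. The histone genes H1-2 and H2BC21 fell by 0.88 and 1.10. Among the 5 largest falls were SHH and MIR3131 and a set of overlapping or very short genes. FAM47E-STBD1, a read-through gene, was at 27.2 ± 22.0 CPM in control cells and 0.192 ± 0.213 with siRNA 1, a call lost without siRNA 1 replicate 1. Summed with FAM47E and STBD1, which it overlaps, it gave 63.8 ± 5.88, 26.4 ± 0.863 and 26.5 ± 2.70 CPM in control, siRNA 1 and siRNA 2. RNY3P8, a Y RNA pseudogene, and ABCF2-H2BE1, a read-through of ABCF2, were at 0 with siRNA 1, at least 3.71-fold and 2.28-fold lower than control. In all, 5349 genes were called with siRNA 1, 2724 higher and 2625 lower, and 1070 of them changed at least 2-fold.

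With siRNA 2, most luminal genes fell and most ER stress genes rose. Luminal genes had 11 falls and no rise among 13, also adjusted over the list alone (median -1.12, camera adjusted p = 4.77e-08, and adjusted p = 0.0280 with an estimated correlation), with the keratin gene KRT19, chosen after its values were seen, falling by 2.35. ER stress and integrated stress response genes had 17 rises and 1 fall among 25 (19 and 1 adjusted over the list alone, median 0.58, camera adjusted p = 0.00109, but adjusted p = 0.325 with an estimated correlation). ASNS, asparagine synthetase, rose by 1.82 ± 0.25 and VLDLR, a lipoprotein receptor gene, by 1.19 ± 0.08. TNC, the extracellular matrix gene tenascin C, rose by 5.81 ± 0.29 and SNAI1, a transcriptional repressor gene, by 1.25 ± 0.37 (list median 3.53, both risen adjusted over the list alone, camera adjusted p = 0.00866, but adjusted p = 0.267 with an estimated correlation), and this list's call was lost with looser filters on low values and under limma.

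PAX1, a developmental transcription factor gene, rose by 5.71 ± 0.30 with siRNA 2 and by 1.61 ± 0.26 with siRNA 1. CDH12, a cadherin gene, was 235-fold higher with siRNA 2 (95% counting interval 64.6 to 1943), from 8 counts over all control libraries, and 4.01-fold with siRNA 1 (0.776 to 37.6). FAM3B, a secreted protein gene, fell by 7.61 ± 0.75, and by 3.15 with siRNA 1. HABP2, a secreted protease gene, and SCGB1D2, a secretoglobin gene, were at 0 with siRNA 2, at least 94.3-fold and 27.2-fold lower than control, and fell by 2.54 and 1.19 with siRNA 1. The mitochondrial cysteine tRNA gene MT-TC had 2 counts in each siRNA 2 library and was 7162-fold lower than control (1487 to 44361). It shares a base with its neighbour MT-TY, which was at 176 CPM in control cells and 335 with siRNA 2, and the sum of both was 393 ± 40.1 CPM in control cells, 275 ± 15.6 with siRNA 1 and 335 ± 20.7 with siRNA 2. The counts thus lay with MT-TY instead of MT-TC, and the fold of MT-TC cannot be read as a fall of its transcript. Androgen-induced genes had 11 falls and 4 rises among 23 (11 and 5 adjusted over the list alone, median -0.28, camera adjusted p = 0.0451, but adjusted p = 0.325 with an estimated correlation), a call lost under limma and without siRNA 1 replicate 1 or any 1 siRNA 2 library. Cytosolic ribosomal proteins had 22 rises and 1 fall among 75 (21 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.0451, but adjusted p = 0.745 with an estimated correlation), a call lost with DESeq2, with offsets for transcript length and GC content, and without any 1 of the siRNA 2 libraries. Nuclear OXPHOS subunits had 23 rises and 2 falls among 43 (24 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.00636, but adjusted p = 0.681 with an estimated correlation). In all, 6328 genes were called with siRNA 2, 3128 higher and 3200 lower, and 1834 of them changed at least 2-fold.

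The comparison of siRNA 1 with siRNA 2 asks where the effects of both sequences differ. SHH was lower by a log2 difference of -3.77 ± 0.23 with siRNA 1 (adjusted p = 8.16e-06), and TMPRSS2 by -1.13 ± 0.05, while KLK3 was lower with siRNA 2, the difference being 1.45 ± 0.20. DNA replication genes were higher with siRNA 1 in 29 of 40 and lower in 1 (31 and 1 adjusted over the list alone, median difference 0.47, camera adjusted p = 2.07e-05, but adjusted p = 0.188 with an estimated correlation). Against control 12 of them rose and none fell with siRNA 1 (10 and none adjusted over the list alone, median 0.15, camera adjusted p = 0.0955), while 1 rose and 18 fell with siRNA 2, also adjusted over the list alone (median -0.20, camera adjusted p = 0.0777). CCNE2, cyclin E2, which overlaps INTS8, had -0.08 with siRNA 1 and -0.94 with siRNA 2, E2F1 -0.13 and -0.44, and the helicase subunit gene MCM5 -0.06 and -0.48. ER stress genes were lower with siRNA 1 in 17 of 25 and higher in 1 (19 and 1 adjusted over the list alone, median -0.80, camera adjusted p = 2.51e-08, but adjusted p = 0.111 with an estimated correlation).

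Cholesterol synthesis genes were lower with siRNA 1 than with siRNA 2 in 16 of 24 and higher in 1 (17 and 1 adjusted over the list alone, median -0.74, camera adjusted p = 1.30e-07, but adjusted p = 0.242 with an estimated correlation). Histones were lower in 8 of 12, also adjusted over the list alone (median -1.04, camera adjusted p = 2.55e-04, but adjusted p = 0.111 with an estimated correlation). H2AC6 was at a log2 fold change of -0.21 with siRNA 1 and 1.35 with siRNA 2. Mitosis genes were lower in 20 of 38 and higher in 3 (24 and 3 adjusted over the list alone, camera adjusted p = 7.12e-04, but adjusted p = 0.448 with an estimated correlation). Cytosolic ribosomal proteins were higher in 36 of 75 and lower in 1 (39 and 1 adjusted over the list alone, camera adjusted p = 7.12e-04, but adjusted p = 0.661 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 10 of 13 (11 adjusted over the list alone, camera adjusted p = 5.74e-04, but adjusted p = 0.422 with an estimated correlation), beside the mitochondrial share of 9.02% against 12.05%, and this call was lost under quantile normalization. MT-CO1, MT-ND3 and MT-ND5 had log2 differences of -0.44, -0.29 and -0.51. In the luminal list 6 were higher and 3 lower with siRNA 1 (7 and 3 adjusted over the list alone, camera adjusted p = 0.00373, but adjusted p = 0.111 with an estimated correlation). Androgen-induced genes had 5 higher and 8 lower of 23 (6 and 9 adjusted over the list alone, camera adjusted p = 0.0239, but adjusted p = 0.188 with an estimated correlation), and that call was lost under limma and without CTRL replicate 3 or siRNA 1 replicate 1. Of 12 ERG-associated genes 6 were higher and 3 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.00524, but adjusted p = 0.300 with an estimated correlation). The luminal and ERG-associated calls were lost under limma.

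In all, 5068 genes differed between the siRNAs, 2646 higher and 2422 lower with siRNA 1, and 1158 of them at least 2-fold. The balance of higher and lower turned under other settings, to 2410 and 2734 in limma with quantile normalization and to 2492 and 2600 in edgeR scaled to library totals. Of the 3317 genes called with both siRNAs in the same direction 1284 also differed in size, 911 with the larger change for siRNA 2 and 373 for siRNA 1. Among 1616 genes called with siRNA 1 alone the difference itself was not called for 561, and among 2595 called with siRNA 2 alone for 786. SLC13A2, a dicarboxylate transporter gene, was 77.5-fold higher with siRNA 1 than with siRNA 2 (95% counting interval 28.4 to 409), and HAO1, a peroxisomal oxidase gene, 74.9-fold (20.4 to 624). ATOH1, a neural transcription factor gene, was 94.1-fold lower (25.7 to 784). The basal keratin gene KRT14 rose by 1.49 with siRNA 1 and fell by 1.65 with siRNA 2. ICAM1, an adhesion gene, rose by 1.27 with siRNA 1 and fell by 0.50 with siRNA 2, CAMK2N1, a kinase inhibitor gene, rose by 0.18 and fell by 0.93, and ENO2, a neuronal enolase gene, fell by 0.44 and rose by 0.53. The recombination gene RAD54L, which overlaps LRRC41, fell by 1.01 with siRNA 2 against 0.09 with siRNA 1, PKM, a pyruvate kinase gene, by 1.08 against -0.17, and the antiviral gene OAS3 by 0.97 against 0.10.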

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

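The tests of the patterns in this part and of the splits were chosen after the results they concern had been seen, although some of the settings they use (DESeq2 size factors, quantile normalization, other scalings of FPKM and leaving out a library) had been chosen before.

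Differences between the effects of siRNA 1 and siRNA 2 that edgeR or camera called come first. The effects differed for 5068 genes, and 416 genes were called in opposite directions. Median log2 differences, siRNA 1 minus siRNA 2, were -0.13 for androgen-induced genes, 0.33 for luminal genes, 0.68 for ERG-associated genes and 0.47 for DNA replication. They were -0.24 for mitosis, -0.74 for cholesterol synthesis, -0.80 for ER stress, 0.29 for cytosolic ribosomal proteins, -0.37 for mitochondrially encoded mRNAs and -1.04 for histones. None of these lists passed camera with an estimated correlation (smallest adjusted p = 0.111). The basal list, with 2 tested genes, had 2.12 (both higher, also adjusted over the list alone, camera adjusted p = 5.36e-04, but adjusted p = 0.157 with an estimated correlation). Mesenchymal transition, also with 2, had -3.12 (1 lower, also adjusted over the list alone, camera adjusted p = 9.38e-04, but adjusted p = 0.111 with an estimated correlation), and without siRNA 1 replicate 1 its call was lost.

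Single genes with a called difference included SPDEF (2.66), KRT14 (3.15), ICAM1 (1.78) and CAMK2N1 (1.11), higher with siRNA 1 on the log2 scale. TNC (-5.66), LUM (-3.76), H2BC21 (-1.62) and ENO2 (-0.97) were lower with siRNA 1. At low counts the fitted differences were 6.24 for SLC13A2, 6.15 for HAO1, -6.48 for ATOH1 and -5.85 for CDH12. HABP2 and SCGB1D2 were at least 16.2-fold and 11.9-fold higher with siRNA 1, and ABCF2-H2BE1 and RNY3P8 at least 108-fold and 5.85-fold higher with siRNA 2. For MT-TC the fitted difference was 12.18, while MT-TC and its overlapping neighbour MT-TY together were at 275 CPM with siRNA 1 and 335 with siRNA 2. ABCF2-H2BE1 and ABCF2, which it overlaps, together were at 151 CPM with siRNA 1 and 146 with siRNA 2.

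The first pattern weighed is the set of 416 genes that the siRNAs moved in opposite directions, SPDEF, KRT14 and ICAM1 among them, a count that was 277 without CTRL replicate 1 and 21 at a log2 change of at least 1. Under the setting of scaling that kept the fewest, limma with quantile normalization, 337 stayed called in opposite directions, and 331 did so with offsets for transcript length and GC content, which argues against either as the whole cause. KMT2C was at 37.6 to 54.8 CPM in the siRNA 1 libraries and at 38.5 to 40.9 with siRNA 2. Every siRNA 2 library thus lay inside the range of siRNA 1, which argues against unequal depth of KMT2C mRNA as the whole cause. The trend of these genes with KMT2C within siRNA 1, carried to the mean KMT2C gap between the siRNAs, gives a median of -0.88% of their difference (5th to 95th percentile -9.63% to 8.70%, and -29.7% to 26.4% from replicates 1 and 2 alone). Called genes favour a small spread within groups, but 1141 genes picked without a test, by opposite log2 changes of at least 0.2, gave a median of -0.67% (-23.4% to 24.2%, and -73.4% to 64.5% from replicates 1 and 2 alone). No conclusion is drawn from the trend. It rests on 3 libraries, whose spread in KMT2C may be technical and would then pull it toward 0. Effects of a single siRNA sequence on other transcripts (the sequences are not given in the sources used here), KMT2C protein, which was not measured, and a difference in handling between the groups stay open, as untested.

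The second pattern is the set of falls among luminal and androgen-induced genes such as KLK3, TMPRSS2 and GATA2, of which 23 were called lower in the average of both siRNAs. At least 22 of these stayed called lower under each other scaling and at least 21 without any single control library. The 23 were chosen on the average, so not all of them fell with each siRNA. SPDEF is among them but rose with siRNA 1, with which 9 of the 13 tested luminal genes fell and 1 rose. Lower KMT2C is the biological explanation that the design names. It may account for the falls that both siRNAs share, as a hypothesis found and examined on the same data. Androgen in the medium was not measured here, and effects that both siRNAs share apart from KMT2C stay open.

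The third pattern is the set of rises among ribosomal protein, ribosome biogenesis and nuclear OXPHOS genes such as RPL11, NOLC1 and UQCRC2, of which 77 were called higher in the average of both siRNAs. Across 12764 genes the average fold change fell with transcript length (Spearman -0.18, across genes, which are not independent replicates), but with offsets for length and GC content 68 of the 77 stayed called higher. Under the other scalings at least 71 did, and the mitochondrial share of counts moved by -1.55 points with siRNA 1 and 1.47 with siRNA 2, which argues against a common shift in that share. The size of the rises is small, with list medians of 0.26 to 0.27, and the list calls were lost with an estimated correlation. A hypothesis that these cells made more ribosomes rests on the 37 ribosomal protein and 15 ribosome biogenesis genes among the 68 kept, but protein or RNA content per cell was not measured here.

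Other splits of the 9 libraries were examined for the counts of called genes. For the average of both siRNAs 1 of 100 splits, the real one, gave 6097 genes, against at most 3250 in the others. This is the smallest share that 100 splits allow, and it argues against chance. The same holds for the 3317 genes called with both siRNAs in the same direction, against at most 1886 in the other splits (1 of 100 as large). The splits cannot tell an effect of the siRNAs from a difference in handling between the groups. For siRNA 1, siRNA 2 and their difference the 10 splits of 6 libraries are too few for a share under 0.05, with 4726, 6654 and 4708 genes in the real split (1 of 10 as large) and at most 2, 0 and 2 in the others. Chance cannot be excluded for the number of lists called, 7 against at most 13 in other splits, of which 41 of 100 gave as many. Those other splits mix libraries of the siRNA groups and the control, so they carry part of the structure between the groups.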

How the results depend on the processing

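The alternatives with counts divided by 4, scaling to library totals, mitochondrial genes left out, and offsets for transcript length and GC content were chosen only after the data had been seen. Over 240 alternative values of 9 main results, 226 stayed within the limits set, 14 moved and 0 reversed. For counts the limits were a fixed factor either way, and wide. Against 416 genes in opposite directions, 279 (without CTRL replicate 2) stayed within them and 277 (without CTRL replicate 1) did not. A count cannot reverse under this rule, so among these results only the KMT2C fold changes could. Raising the filter to an FPKM of at least 5 left 7057 genes to test, which by itself lowers the counts, to 3480 for siRNA 1, 3851 for siRNA 2, 3852 for the average, 3197 for the difference and 2178 for both siRNAs in the same direction. Asking for an absolute log2 fold change of at least 1 gave 1070, 1834, 1192, 1158 and 633, with 21 genes in opposite directions. Leaving out 1 library gave 277 (without CTRL replicate 1) to 431 (without siRNA 1 replicate 1) genes in opposite directions, against 416 with all; the cause was not tested. It gave 4511 to 5082 genes for siRNA 1, 5508 to 6706 for siRNA 2, 5175 to 6273 for the average and 4109 to 4981 for the difference. KMT2C stayed between -2.98 and -2.69 with siRNA 1 and between -3.02 and -2.95 with siRNA 2. Of the lists called for the average, 7 in all, an estimated correlation left 1, and fry called 20, a test that does not compare a list with other genes. Every one of the 7 was called in each alternative run for the lists except the estimated correlation. For named genes 4532 of 4640 alternative values stayed on their side of the threshold, 52 became weaker and 56 stronger, and for lists 3238 of 3544, with 101 weaker and 205 stronger; 0 reversed. In the average of both siRNAs the calls of EGR1, H1-2, NFKB2 and TET2 were lost without CTRL replicate 3, that of ID1 without CTRL replicate 2, that of KDM6A without CTRL replicate 2 and under some limma settings, and that of ICAM1 without CTRL replicate 2 or 3. H2BC21, near the threshold, was lost without any 1 library except siRNA 1 replicate 1, and the calls of KMT2D and HSPA4 with the length and GC offsets; the cause was not tested. Under most limma settings the HABP2 difference and the ABCF2-H2BE1 fall with siRNA 1, at very low counts, were not called. Between 82.0% and 99.7% of the 6097 genes called for the average that were tested again were also called under the other settings, and with an FPKM of at least 5, which leaves 3766 of them to test, 3760 were. The share of called genes that were higher turned about an even split, from 44.2% to 55.1% for the average, 48.3% to 54.9% for siRNA 1, 45.2% to 55.6% for siRNA 2 and, for the difference, 46.9% (limma with quantile normalization) to 60.8% (limma with FPKM scaled to equal totals). With the replicate number as a block the fit called 5007, 6070, 5838 and 4766 genes for siRNA 1, siRNA 2, the average and the difference, but the labels do not pair the libraries, and same-number libraries of different groups correlated at -0.0688 to 0.0393 against -0.0832 to 0.0912 for different numbers after group means were removed. Depth limits the very low genes, where about 4 counts stand for 1 fragment. For log2 changes of 0.5 the test recovered 17.9% of simulated changes in the average. That simulation gave 125 calls against 6097 in the data, so its adjusted threshold was stricter and its share does not carry over.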

Other observations

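The test of genes near KMT2C was chosen before its result was seen; the KEGG pathway tests and the genes named here were chosen after.

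Further hedgehog pathway genes fell beside the ligands. Of 32 tested genes of the KEGG hedgehog signaling pathway 19 fell and 3 rose in the average of both siRNAs (median -0.35, camera adjusted p = 5.98e-05, but adjusted p = 0.434 with an estimated correlation). PTCH1, the hedgehog receptor and itself a target of the pathway, fell by 0.92 with siRNA 1 and 0.88 with siRNA 2, the transcription factor gene GLI3 by 1.44 and 1.90, and the co-receptor gene CDON by 0.94 and 1.06. SMO, the signal transducer, had -0.16 and 0.02 and passed neither test. Sphingolipid metabolism had 23 falls and 4 rises among 37 genes (median -0.46, camera adjusted p = 7.90e-04, but adjusted p = 0.459 with an estimated correlation). The ceramidase gene ACER2 fell by 3.16 and 2.93, the sialidase gene NEU1 by 1.64 and 1.61, and the ceramide desaturase gene DEGS1 by 1.10 and 1.46. Lysosome genes had 49 falls and 11 rises among 96 (median -0.27, camera adjusted p = 0.00236, but adjusted p = 0.474 with an estimated correlation), with LAMP2, a lysosomal membrane protein, falling by 0.86 and 2.33 and CTSA, a carboxypeptidase, by 0.61 and 2.17, while the protease gene CTSO rose by 1.18 and 1.35.

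Tight junction genes had 52 falls and 16 rises among 114 in the average (median -0.20, camera adjusted p = 0.00236, but adjusted p = 0.434 with an estimated correlation). The scaffold genes CGN and TJP3 fell by 1.66 and 3.99 and by 2.49 and 2.21, the barrier gene CLDN8 by 2.20 and 2.65 and occludin, OCLN, by 1.80 and 1.38, while CLDN15, which forms ion channels, rose by 1.36 and 1.36. With siRNA 2 the aminoacyl-tRNA biosynthesis pathway had 21 rises and 4 falls among 42 genes (median 0.24, camera adjusted p = 0.0484, but adjusted p = 0.434 with an estimated correlation), and the tRNA synthetase genes EPRS1 and CARS1 rose by 0.98 and 1.36, against 0.02 and -0.17 with siRNA 1. Genes that the siRNAs moved in opposite directions included the zinc-binding glycoprotein gene AZGP1 (1.26 with siRNA 1 and -2.30 with siRNA 2), the muscle protein gene MYBPC1 (1.17 and -2.54), the growth factor binding protein gene IGFBP5 (-1.54 and 2.68) and the serine synthesis gene PSAT1 (-1.97 and 1.30). Over 268 pathways camera called 1 up and 17 down for the average, and none with an estimated correlation.

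SHH lies 3.36 Mb from KMT2C on the same chromosome, so the hypothesis of a local effect on the region was examined. Of 71 tested genes within 5 Mb of KMT2C 15 rose and 19 fell, and their median log2 fold change was -0.10. That lay at percentile 13.7 of 168 runs of as many consecutive genes elsewhere, whose medians ranged from -0.25 to 0.20. A shift of the region beyond that of other runs was thus not detected. A smaller shift is not excluded, and an effect on SHH alone was not tested.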
